A study of Mus musculus with 8 samples.

How the data were processed

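RNA was measured in 8 libraries of mouse 2-cell embryos, 4 injected with CasRx alone (control) and 4 injected with CasRx directed at Polq (knockdown-labelled), each from a pool of 5 embryos. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina. The deposited values are expected counts per gene, one column per library, not normalised. Per the submitters' processing notes, the authors used Trim Galore 0.6.10, STAR 2.7.3a and RSEM 1.2.28 with the genome build GRCm38 (mm10). The annotation release, the strand setting, the read length, any removal of duplicate reads and any filter are not given in the sources used here. RSEM divides reads that match several genes among them by estimation, so the counts of gene families with near-identical copies (Zscan4, Omt2, Tcstv, Usp17l, Obox and Trim43 genes, and ribosomal protein genes with processed pseudogenes) are uncertain. With the strand setting unknown, reads of genes that overlap on opposite strands cannot be told apart. Among the genes named, Ino80e, Ankrd44, Plk1, Rbbp8, Xrcc4, Eme1, Palb2, Ercc1, Pola1, Ei24, Cdc25c, Slc7a11, Dnajb9, Wdr43, Trim43c, Obox3, Cnot2, Tet3, Lin28a, Ccne2, Rps2, Rpl18, mt-Nd6, Cox4i1, Brca2, Psat1 and Btg4 overlap an annotated gene on the other strand.

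The deposited table held 55487 genes, of which 26410 had a count in at least 1 library. Expected counts were rounded to whole numbers, which altered 4.22% of the values. Library totals were 33311665 to 43748621 counts in the controls and 4726159 to 33650050 counts in the knockdown-labelled libraries. The labels mention no molecular identifiers, and without them amplified copies of a molecule count as separate reads, so that a count is not a number of molecules. Intervals from edgeR include the spread between libraries.

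Genes with low counts were removed with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 13146 genes. Library sizes were scaled by the trimmed mean of M values (TMM). The groups were compared with edgeR 4.0.16 (quasi-likelihood test with robust hyperparameters, group as the only term) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are knockdown-labelled minus control, with standard errors derived from the estimate and its F statistic and 95% intervals from the same degrees of freedom. CPM values (counts per 1000000) are TMM-scaled, and levels are given as mean ± SD of 4 libraries, controls first. The common biological coefficient of variation was 0.987. Polq levels were also compared by a 2-sided exact permutation test over all 70 assignments of 4 of 8 libraries.

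The test, the samples, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 26 gene lists cover DNA repair, stress responses, the early embryo, the cell cycle, housekeeping functions and markers of other cells. The 25 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether the genes of a list move one way. Of the list members, 4 were not found in the table under the symbols used. The genes named are Polq, the 5 genes with the smallest p in each direction because none passed, and the 2 members of each list with the smallest p, except that some genes are not reported here. For the first of these the rule's other criteria were kept, namely an average log2 CPM of at least 2, groups that do not overlap, and no symbol of a predicted gene. The rule left that open where no gene passed. The most abundant member of each list was chosen after its values were seen.

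Alternatives were DESeq2 size factors, upper-quartile scaling, library totals alone, leaving out mitochondrially encoded genes, no filter on low counts, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0 (144 genes with no adjusted p stayed out), limma-voom, edgeR without robust hyperparameters, a block for the replicate number, stricter thresholds (adjusted p under 0.01, or a fold change of at least 2), and leaving out each library in turn. After seeing the data, 4 more were added: thinning all libraries to the smallest total, leaving out knockdown-labelled replicates 1, 2 and 3, keeping only genes with a mean of at least 50 CPM, and limma-voom with sample quality weights.

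The procedure was tested on simulated data with the means and library sizes of the 13146 genes. Genes at 10 CPM or more were changed, 100 by 2-fold and 100 by 4-fold together in each simulation. With the measured spread it called 6 of 100 genes changed 2-fold and 50 of 100 changed 4-fold, with 2 false calls among 58. With a dispersion of 0.05 it called 83 of 100 and 100 of 100, with 9 false calls among 192. A shifted list of 40 genes was recovered and 0 of the other lists were called. The simulated genes varied independently, so this does not test false calls of lists whose members correlate. Positions and exonic lengths come from the GENCODE M21 annotation of GRCm38, in which 97.41% of the tested genes were found by symbol. It may differ from the authors' annotation.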

Results

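The series measured RNA from mouse embryos at the 2-cell stage by sequencing, to ask how knockdown of Polq with CasRx affects the whole transcriptome. CasRx is an RNA-guided nuclease that cuts RNA and not DNA, and Polq encodes DNA polymerase theta, the central enzyme of alternative (theta-mediated) end joining of DNA breaks. Zygotes were injected 20 h after human chorionic gonadotropin, and RNA was taken 10 h later from pools of 5 embryos. The 4 control samples received CasRx alone, and the 4 knockdown-labelled samples received CasRx directed at Polq. The series text calls the 4 samples of a group biological replicates. The labels name no control guide, and the position of the Polq guide is not given in the sources used here. Control replicates 1 to 4 held 33311665, 35007614, 43748621 and 40702806 counts, and knockdown-labelled replicates 1 to 4 held 4726159, 8627403, 8100969 and 33650050 counts. Between 16015 and 18217 genes had at least 1 count in the control libraries, and between 14487 and 16908 in the knockdown-labelled libraries.

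Polq RNA was present in all 8 libraries and was not separated between the groups. Its normalised level was 34.6, 49.7, 40.1 and 32.7 counts per 1000000 (CPM) in control replicates 1 to 4, a mean of 39.3 ± 7.65 (SD, n = 4). It was 16.9, 38.9, 29.2 and 41.1 CPM in knockdown-labelled replicates 1 to 4, a mean of 31.5 ± 11.03 (SD, n = 4). Knockdown-labelled replicates 2 and 4 lay inside the range of the controls, and replicates 1 and 3 lay below all 4 controls. These levels rest on 1132, 1579, 1754 and 1404 counts in the controls and on 85, 320, 253 and 1310 counts in the knockdown-labelled libraries. Polq (ENSMUSG00000034206.15) lies on the plus strand of chromosome 16 from 37011786 to 37095417 (GRCm38), a protein-coding gene with 31 separate exonic regions and no annotated gene overlapping it.

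The fitted Polq level of the knockdown-labelled group was 80.4% of the control level, with a 95% interval from 47.8% to 135% (edgeR log2 fold change −0.32, SE 0.34, adjusted p = 1.0). A 2-sided exact permutation test of the 8 levels gave p = 0.343, where the smallest p that 4 against 4 libraries can give is 0.0286. A Polq level below 47.8% of control lay outside the interval. With 1 library left out the log2 fold change ran from −0.47 without knockdown-labelled replicate 4 to −0.11 without knockdown-labelled replicate 1, and it was −0.18 without control replicate 2. With replicate 4, which has the highest Polq level of its group, as the single knockdown-labelled library, a setting chosen after seeing the data, it was 0.073. Because Polq did not separate the groups, the libraries are named by their label throughout, and each direction given here is knockdown-labelled minus control.

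**Figure D1:**
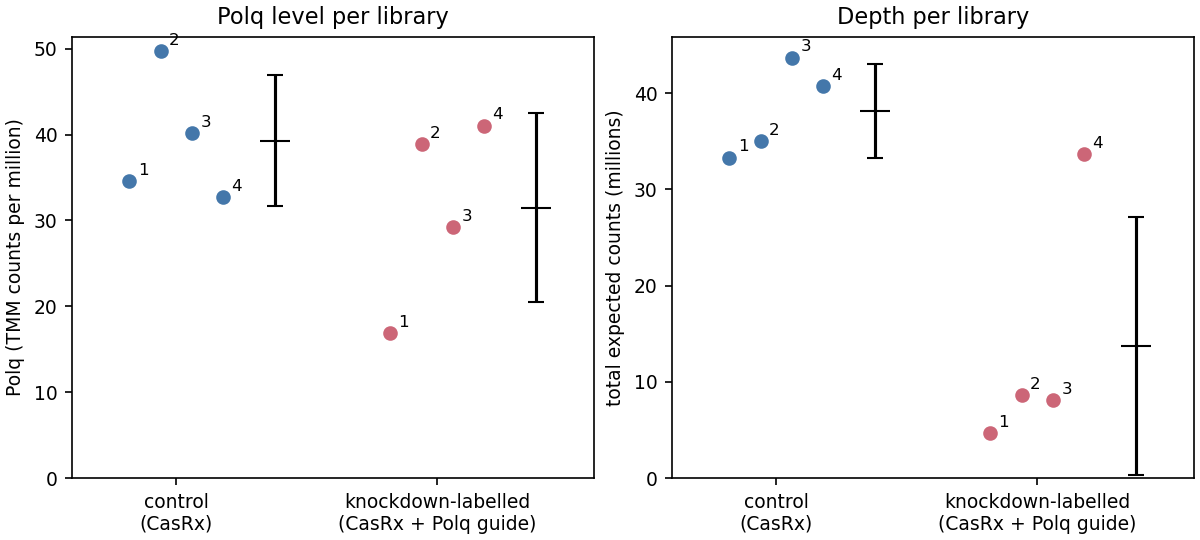
Polq level in TMM-normalised CPM (left) and total expected counts in units of 1000000 (right) in each library, with the replicate number beside each point and bars for the mean ± SD of 4 libraries. Knockdown-labelled replicates 2 and 4 lie within the control range of 32.7 to 49.7 CPM, and knockdown-labelled replicates 1, 2 and 3 hold 4726159 to 8627403 counts against 33311665 or more in each control.

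No gene passed the transcriptome-wide edgeR test between the groups, while DESeq2 called 20, Gjc1 and Ino80e among them. The rule kept genes with an average log2 CPM of at least 2, groups that did not overlap and no predicted symbol. Of these, the genes higher in the knockdown-labelled libraries with the smallest edgeR p were Gjc1, Ino80e, Fam118a, Mrpl4 and Mul1. Gjc1 is a gap junction protein and Ino80e a subunit of a chromatin remodelling complex. Mrpl4 is a protein of the large mitochondrial ribosomal subunit, and Mul1 a ubiquitin ligase of the mitochondrial outer membrane. Gjc1 had 1 count in control replicate 3 and 0 in the other controls, against 7, 135, 98 and 358 counts in knockdown-labelled replicates 1 to 4 (10.1 ± 6.28 CPM). Ino80e was at 0.338 ± 0.173 CPM in the controls and 7.94 ± 3.65 CPM in the knockdown-labelled libraries, and Fam118a at 16.4 ± 6.06 and 45.7 ± 11.1 CPM (log2 fold change 1.48, SE 0.37). Mrpl4 was at 6.39 ± 1.38 and 22.3 ± 11.2 CPM (1.80, SE 0.47), and Mul1 at 3.09 ± 1.35 and 16.3 ± 12.3 CPM (2.39, SE 0.68). Without knockdown-labelled replicate 2 the Mul1 mean of that group was 10.2 CPM (log2 fold change 1.74).

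Of the genes that met the same criteria, those lower in the knockdown-labelled libraries with the smallest edgeR p were Cmc2, Mrps14, Gmcl1, Ankrd44 and Triqk. Cmc2 encodes an assembly factor of cytochrome c oxidase, and Mrps14 a protein of the small mitochondrial ribosomal subunit. Cmc2 was at 38.7 ± 8.80 CPM in the controls and 14.8 ± 4.01 CPM in the knockdown-labelled libraries (log2 fold change −1.38, SE 0.34). Mrps14, the most abundant of these genes, was at 781 ± 53.1 and 549 ± 30.9 CPM (−0.51, SE 0.13). Gmcl1 was at 96.5 ± 33.5 and 37.0 ± 12.3 CPM (−1.38, SE 0.34), Ankrd44 at 138 ± 23.4 and 76.7 ± 12.5 CPM (−0.84, SE 0.21), and Triqk at 136 ± 31.1 and 63.6 ± 18.9 CPM (−1.10, SE 0.28). In each of these 10 genes, as the criteria required, the 4 knockdown-labelled libraries lay on one side of the 4 controls. The same held in 392 of the 13146 genes tested (2.98%), where chance gives 2.86%. In GRCm38, Gjc1 lies on chromosome 11 from 102799579 to 102819700, Ino80e on chromosome 7 from 126850960 to 126862377, Fam118a on chromosome 15 from 85028948 to 85062830, Mrpl4 on chromosome 9 from 21002738 to 21008839, and Mul1 on chromosome 4 from 138434671 to 138442265. Cmc2 lies on chromosome 8 from 116888685 to 116921455, Mrps14 on chromosome 1 from 160195215 to 160202170, Gmcl1 on chromosome 6 from 86691768 to 86733383, Ankrd44 on chromosome 1 from 54645340 to 54926387, and Triqk on chromosome 4 from 12906838 to 12983553. All 10 are annotated as protein-coding, and the gene spans of Ino80e and Ankrd44 overlap other annotated genes, whose reads the counting may share with them.

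The edgeR quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 144 higher and 225 lower genes, 369 in all. Evenly distributed p-values would give 657. The other splits of the 8 libraries into 4 and 4 gave a median of 311 in the same test. Limma-voom also called 0 genes, with 863 at an unadjusted p under 0.05. DESeq2 called 14 genes higher and 6 lower, Gjc1 and Ino80e among them, and 19 of these 20 had at least 1 library with under 10 counts. The precision depended on abundance: the median 95% interval of a fold change reached 4.43-fold either way for genes at 5 to 10 CPM, 1.62-fold at 50 to 100 CPM and 1.32-fold above 500 CPM. In counts simulated with the measured spread, 50 of 100 genes at 10 CPM or more that were changed 4-fold were called, and 6 of 100 changed 2-fold. These genes were changed together in 1 simulation. With fewer changed genes the adjusted threshold is stricter, so these shares can overstate what the real test would detect.

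None of the 5 lists of DNA repair genes passed the test between the groups as a set, and no member passed by itself. The median range of a list gives the lowest and highest values of its median with 1 of the 8 libraries left out. Each such fit has its own filter on low counts, so that the median over 8 libraries can lie outside the range. Among 18 tested genes of alternative end joining, the pathway of Polq, 7 had positive and 11 negative log2 fold changes (median −0.13, median range −0.32 to −0.12, camera adjusted p = 0.898). The median was −0.32 and −0.28 without knockdown-labelled replicates 2 and 3. Plk1, a mitotic kinase, was at 4.57 ± 1.48 CPM in the controls and 13.7 ± 6.55 CPM in the knockdown-labelled libraries, and Rbbp8, the end-resection factor CtIP, at 42.9 ± 11.004 and 71.8 ± 27.7 CPM. The 18 genes of classical non-homologous end joining had a median of 0.09 (median range −0.057 to 0.23, adjusted p = 0.881). Xrcc4, a partner of DNA ligase IV in that pathway, was at 31.3 ± 12.8 CPM in the controls and 8.64 ± 4.24 CPM in the knockdown-labelled libraries (log2 fold change −1.86, SE 0.51). It had the smallest p of any list when adjusted over the list alone, 0.0823, and so did not pass. Rnf168 of the same list was at 52.6 ± 25.5 and 37.4 ± 7.06 CPM.

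The 38 tested genes of homologous recombination had a median log2 fold change of −0.09, a mean of 0.08 and an upward camera direction, so that these differed in sign (adjusted p = 0.881). That median was positive without control replicate 3 or 4 (0.052 and 0.055) and without knockdown-labelled replicate 2 or 4 (0.0057 and 0.038). Eme1, a subunit of a structure-specific endonuclease, was at 11.8 ± 5.76 CPM in the controls and 3.30 ± 1.59 CPM in the knockdown-labelled libraries, and Palb2, the partner of Brca2, at 18.5 ± 2.77 and 30.8 ± 4.24 CPM. The 20 genes of the Fanconi anaemia pathway had a median of 0.11 (median range 0.029 to 0.27, adjusted p = 0.477), with Fancb at 1.26 ± 0.875 and 11.1 ± 10.8 CPM and Ercc1 at 119 ± 87.1 and 184 ± 88.0 CPM. The Fancb mean was 6.04 CPM without knockdown-labelled replicate 4, and the Ercc1 mean was 78.8 CPM without control replicate 1. The 22 DNA polymerase genes had a median of −0.20 (adjusted p = 0.83). The median was −0.023 without knockdown-labelled replicate 4 and −0.091 without control replicate 1. The polymerase epsilon subunit Pole3 was at 138 ± 35.5 and 86.0 ± 8.73 CPM and the polymerase alpha subunit Pola1 at 99.0 ± 11.05 and 64.3 ± 25.5 CPM.

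The 6 lists of stress response genes did not pass as sets either. The 23 tested p53 targets had a median log2 fold change of −0.09 (camera adjusted p = 0.881), with Ei24 at 18.2 ± 4.09 CPM in the controls and 35.4 ± 13.1 CPM in the knockdown-labelled libraries, and Trp53inp1 at 133 ± 8.55 and 88.4 ± 29.1 CPM. The median of the p53 targets was 0.076 and 0.098 without control replicates 2 and 3 and −0.31 without knockdown-labelled replicate 4. The 20 genes of checkpoint and damage signalling had a median of −0.10, a mean of 0.06 and a downward camera direction (median range −0.23 to 0.025, adjusted p = 0.896). Cdc25c, a phosphatase that promotes entry into mitosis, was at 36.5 ± 9.75 and 60.3 ± 10.6 CPM, and Ppm1d, a phosphatase that dampens damage signalling, at 3.30 ± 2.25 and 12.7 ± 11.6 CPM. The Ppm1d mean was 6.87 CPM without knockdown-labelled replicate 2. The 21 genes of the apoptosis machinery had a median of −0.16 (adjusted p = 0.881). The median was −0.39 without knockdown-labelled replicate 4 and −0.045 without control replicate 2. The survival factor Mcl1 was at 34.0 ± 6.71 and 59.6 ± 11.1 CPM.

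In the interferon and double-stranded RNA response 25 of 34 genes were too low to test, Isg15, Ifit1, Oas1a and Ifnb1 among them, and the other 9 summed to 56.6 ± 12.3 CPM in the controls and 57.1 ± 10.5 CPM in the knockdown-labelled libraries. Their median log2 fold change was −0.03, with a mean of 0.17 and an upward camera direction (adjusted p = 0.798). The median was 0.37 and 0.60 without control replicates 1 and 4 and 0.035 without knockdown-labelled replicate 3. Mavs, the mitochondrial adaptor of RNA sensing, was at 0.471 ± 0.943 and 4.07 ± 2.31 CPM. The RNA sensor Ddx58 was at 11.7 ± 17.4 and 4.56 ± 2.12 CPM, a direction that turned without control replicate 3 (log2 fold change 0.58 in place of −1.35). Without that library the Ddx58 control mean was 3.05 CPM, and without control replicate 4 the Mavs control mean was 0. The 21 genes of the integrated and ribotoxic stress response had a median of −0.10 (adjusted p = 0.980). The median was 0.12 without control replicate 4 or knockdown-labelled replicate 2, and 0.016 without control replicate 2. The immediate early gene Egr1 was at 4.40 ± 3.01 and 0.251 ± 0.501 CPM and the cystine transporter Slc7a11 at 28.2 ± 5.25 and 14.2 ± 8.25 CPM. Egr1 was at 0 in knockdown-labelled replicates 1, 2 and 3. The 24 genes of the heat shock and unfolded protein response had a median of −0.13 (median range −0.23 to −0.025, adjusted p = 0.798), with the chaperone Dnajb9 at 829 ± 98.3 and 995 ± 132 CPM and Bag3 at 6.55 ± 3.64 and 1.93 ± 1.37 CPM.

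Genes of the maternal-to-zygotic transition showed no member past the test in any of the 7 lists on the early embryo. The 43 nucleolar and ribosome biogenesis genes, which are switched on with the zygotic genome, had 32 positive log2 fold changes and a median of 0.28, without passing as a set (median range 0.11 to 0.33, camera adjusted p = 0.150). Utp20, a ribosome assembly factor, was at 8.11 ± 1.78 CPM in the controls and 19.4 ± 5.54 CPM in the knockdown-labelled libraries, and Wdr43 at 207 ± 61.6 and 278 ± 61.0 CPM. The 55 maternal oocyte transcripts had 40 negative log2 fold changes and a median of −0.12 (median range −0.33 to −0.0051, adjusted p = 0.279), with Nlrp9a at 109 ± 43.5 and 61.5 ± 25.2 CPM and the oocyte transcription factor Lhx8 at 11.3 ± 6.88 and 2.86 ± 2.48 CPM. The Lhx8 mean was 1.79 CPM without knockdown-labelled replicate 2. The nucleolar and maternal lists both passed without control replicate 1 (adjusted p = 0.0343 and 0.0468) and without knockdown-labelled replicate 1 (0.0101 for each). With any other single library left out the adjusted p ran from 0.175 to 0.591 and from 0.175 to 0.909. The nucleolar list also passed with the stricter filter on low counts (adjusted p = 0.0276). With an estimated correlation the adjusted p was 0.921 for each.

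The 30 genes of the maternal mRNA clearance machinery had a median log2 fold change of −0.17 (median range −0.19 to −0.093, adjusted p = 0.798). Cnot2 and Cnot6l, both of the deadenylase complex that removes poly(A) tails, were at 46.2 ± 14.8 and 143 ± 46.5 CPM in the controls and at 20.8 ± 3.30 and 90.0 ± 20.3 CPM in the knockdown-labelled libraries. The 38 genes of the 2-cell burst, which are transcribed briefly at this stage, had a median of −0.0043 (0.018 with DESeq2 size factors and 0.040 with library totals alone), a mean of 0.05 and an upward camera direction (median range −0.25 to 0.17, adjusted p = 0.881). Spz1 was at 40.4 ± 11.7 and 24.7 ± 7.13 CPM and Zfp809 at 121 ± 42.6 and 177 ± 51.8 CPM. The 32 other zygotic genome activation genes had a median of 0.15 (median range 0.077 to 0.25, adjusted p = 0.477), with Obox3 at 517 ± 39.2 and 625 ± 131 CPM and Trim43c at 210 ± 54.9 and 273 ± 37.8 CPM, both uncertain because near-identical copies can share their reads. The 37 epigenetic regulators had a median of 0.0098 (median range −0.049 to 0.21, adjusted p = 0.83), with the 5-methylcytosine dioxygenases Tet1 at 20.3 ± 4.69 and 32.9 ± 2.96 CPM and Tet3 at 25.7 ± 6.90 and 40.6 ± 8.12 CPM. The 18 pluripotency and lineage regulators had a median of 0.17 (median range −0.028 to 0.28, adjusted p = 0.881), with Zfp42 at 3.83 ± 1.77 and 11.3 ± 5.64 CPM and Lin28a at 4.37 ± 4.89 and 0.644 ± 0.624 CPM. The Lin28a means were 2.07 CPM without control replicate 2 and 0.410 CPM without knockdown-labelled replicate 4.

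The 79 cytosolic ribosomal protein genes rose as a set relative to the other genes in the knockdown-labelled libraries, by a median log2 fold change of 0.15, with 66 positive and 13 negative members (camera adjusted p = 0.0194 with a preset correlation of 0.01). With an estimated correlation, which was 0.49 between members, the adjusted p was 0.921, and no list passed. With fry it was 0.832. No member passed by itself. Rps2 was at 37.8 ± 5.96 CPM in the controls and 58.2 ± 13.7 CPM in the knockdown-labelled libraries, and Rpl18 at 93.8 ± 19.1 and 137 ± 31.7 CPM, both with processed pseudogenes in the genome that can share their reads. The mean log2 level of the list was 8.04, 7.32, 7.49 and 7.79 in control replicates 1 to 4 and 7.51, 7.95, 8.01 and 7.90 in knockdown-labelled replicates 1 to 4, so that the groups overlapped (exact permutation p = 0.343). The call was lost without control replicate 2 or 3 (adjusted p = 0.492 and 0.524) and without knockdown-labelled replicate 2, 3 or 4 (0.584, 0.583 and 0.226). Without control replicate 1 the adjusted p was 3.04e-05, and without knockdown-labelled replicate 1 it was 0.000137. The median log2 fold change was 0.31 and 0.24 without these, and 0.061 and 0.095 without control replicates 2 and 3.

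**Figure D2:**
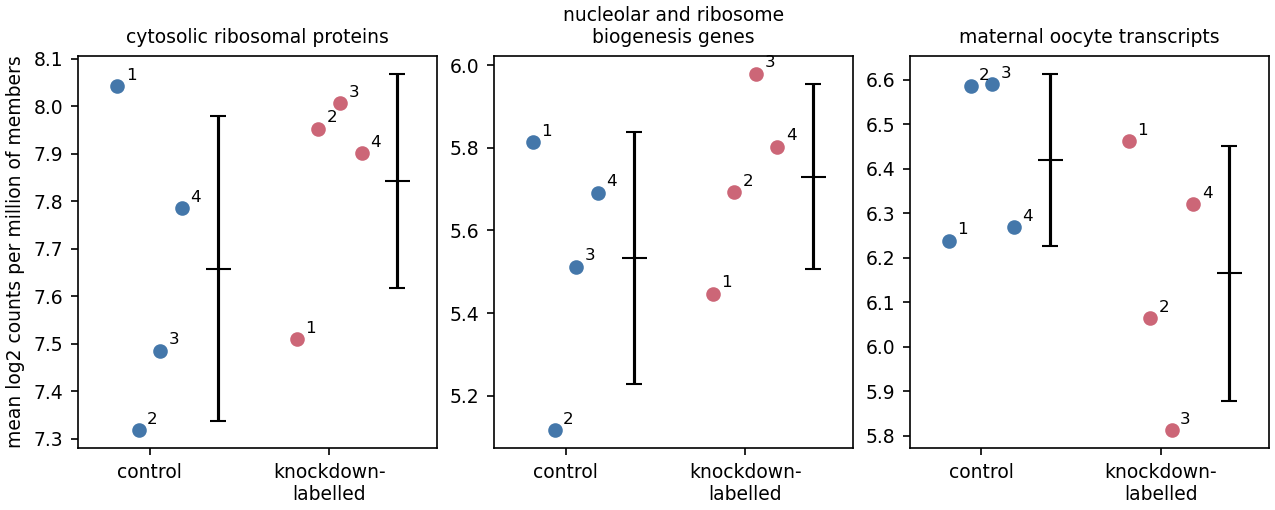
Mean log2 CPM over the tested members of 3 gene lists in each library, with the replicate number beside each point and bars for the mean ± SD of 4 libraries; the vertical axes do not start at 0. The groups overlap in all 3 lists, and within the controls the ribosomal protein list runs from 7.32 to 8.04.

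No list of cell cycle or energy metabolism genes passed as a set. The 39 tested genes of G2 and M phase had 25 positive log2 fold changes and a median of 0.11 (median range 0.0080 to 0.15, camera adjusted p = 0.477), with Ccnb2, a mitotic cyclin, at 8.49 ± 4.45 CPM in the controls and 26.5 ± 9.23 CPM in the knockdown-labelled libraries. The 35 genes of S phase and replication had a median of −0.05 (median range −0.087 to 0.0011, adjusted p = 0.881), with Gins3 at 14.6 ± 6.96 and 4.82 ± 2.31 CPM and Ccne2 at 94.7 ± 28.7 and 63.6 ± 6.32 CPM. The 12 mitochondrially encoded mRNAs had a median of 0.13 (adjusted p = 0.798). The median was −0.075 without knockdown-labelled replicate 2 and −0.0033 without control replicate 4. The mRNA mt-Nd2 was at 22211 ± 4528 and 18962 ± 5491 CPM and mt-Nd6 at 921 ± 165 and 1010 ± 136 CPM. Mitochondrially encoded genes, ribosomal RNAs included, took 23.9, 26.9, 22.0 and 17.8% of counts in control replicates 1 to 4 and 20.2, 27.7, 20.5 and 24.3% in knockdown-labelled replicates 1 to 4. The 45 nuclear genes of oxidative phosphorylation had a median of 0.02 (median range −0.080 to 0.12, adjusted p = 0.881), with Atp5c1 at 69.1 ± 17.8 and 110 ± 17.4 CPM and Cox4i1 at 262 ± 73.0 and 381 ± 72.2 CPM.

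No list of markers of other cells that can come with embryos passed the test. Of 26 cumulus and granulosa cell markers 2 were high enough to test, Tnfaip6 at 6.11 ± 7.18 CPM in the controls and 3.16 ± 5.04 CPM in the knockdown-labelled libraries and Amhr2 at 4.30 ± 2.698 and 5.32 ± 2.44 CPM, too few for a set test. The 5 tested sperm transcripts had a median log2 fold change of 0.31 (camera adjusted p = 0.881). The median was −0.44 without knockdown-labelled replicate 3 and −0.021 without control replicate 3. Ldhc was at 27.8 ± 14.9 and 34.4 ± 29.0 CPM and Tekt1 at 3.94 ± 3.02 and 2.57 ± 1.91 CPM. The directions of Tnfaip6, Amhr2 and Ldhc turned when 1 library was left out, and that of Tekt1 turned in limma-voom. The Tnfaip6 means were 2.75 CPM without control replicate 2 and 0.650 CPM without knockdown-labelled replicate 4, and the Ldhc mean was 20.4 CPM without knockdown-labelled replicate 3. The 6 tested oviduct and blood markers had a median of 0.25 (median range 0.14 to 0.60, adjusted p = 0.477). The median was −0.046 with the stricter filter on low counts. The oviduct glycoprotein Ovgp1 was at 1.11 ± 0.691 and 4.44 ± 2.44 CPM and the epithelial adhesion gene Epcam at 55.8 ± 12.02 and 82.5 ± 31.5 CPM.

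**Figure D3:**
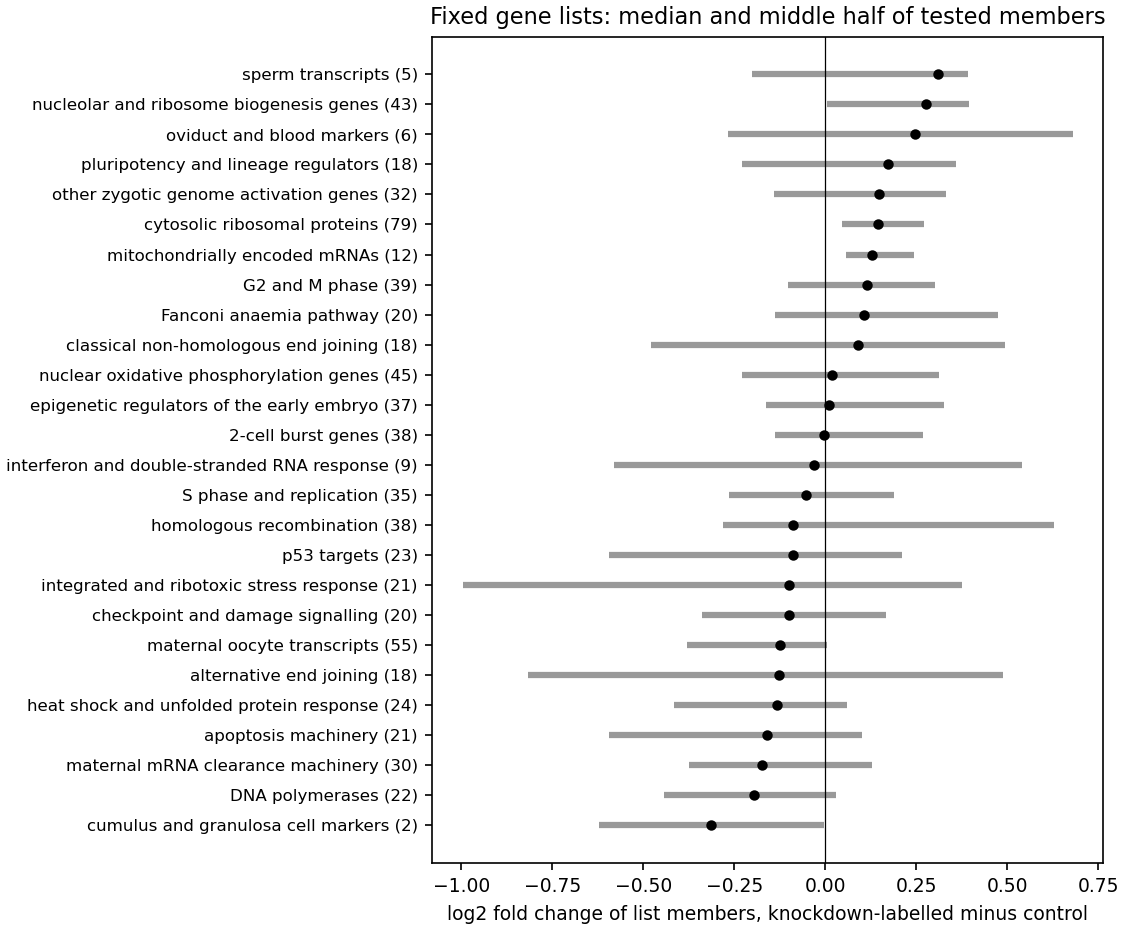
Median (points) and interquartile range (bars) of the edgeR log2 fold changes of the tested members of each of the 26 gene lists, knockdown-labelled minus control, with the number of tested members after each name. The medians lie between −0.31 for the 2 cumulus and granulosa cell markers and 0.31 for the sperm transcripts, and the cytosolic ribosomal proteins, at 0.15, are the list that passed the set test with the preset correlation (camera adjusted p = 0.0194), a call lost with an estimated correlation (adjusted p = 0.921). The cumulus and sperm medians took the other sign when 1 library was left out.

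In none of the 26 lists did a member pass when adjusted over the list alone, as none passed when adjusted over all 13146 genes (edgeR). In 14 of the 26 lists the median log2 fold change took the other sign when 1 library was left out. Across tested genes, which are not independent replicates, Pearson correlations of log2 levels between libraries had a median of 0.737 over the 12 pairs within groups and 0.740 over the 16 pairs between groups.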

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

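Sets of 4 values numbered 182 (3 library measures, 26 list levels and the named genes, in each group). Of these, 14 held a library far from the other 3. Chance would give about 9.1 only if values were normally distributed and sets independent. Gene levels entered as CPM without a log scale. A set whose other 3 libraries have the same value is always flagged, as for Gjc1 and Mavs in the controls. The same holds for Egr1 in the knockdown-labelled libraries. Whether 14 exceeds chance therefore cannot be decided from this comparison. Of the tests in this part, those on depth and on the number of molecules were chosen after the zeros had been seen, and the test of zeros by group was fixed before its result.

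Knockdown-labelled replicate 4 held 33.7 (in units of 1000000 counts) against 4.7 to 8.6 in the other knockdown-labelled libraries. It also stood apart in the mean log2 level of the apoptosis list, at 4.35 against 3.77 to 3.86, but lay within the control levels of 3.51 to 4.42. By the summed level of that list it did not stand apart, at 1730 CPM against 1731, 1535 and 1298 CPM in knockdown-labelled replicates 1 to 3. In knockdown-labelled replicate 4 Mavs was at 7.52 CPM against 2.67 to 3.12 CPM, Egr1 at 1.003 CPM against 0 in the other 3, and Tnfaip6 at 10.7 CPM against 0 to 1.16 CPM. Knockdown-labelled replicate 2 stood apart in Mrpl4, at 39 CPM against 15.8 to 18.0 CPM, and in Ppm1d, at 30.1 CPM against 6.58 to 7.34 CPM. Knockdown-labelled replicate 3 stood apart in Ddx58, at 1.39 CPM against 5.55 to 5.70 CPM, and in Cnot2, at 25.65 CPM against 18.6 to 19.8 CPM. Control replicate 4 stood apart in the interferon list, at a mean log2 level of 2.55 against 0.607 to 0.616. It did not by the summed level of that list, 64.0 CPM against 55.6, 39.7 and 67.2 CPM in control replicates 1 to 3. The mean log2 level gives low genes the same weight as high ones. Control replicate 4 also stood apart in Mavs, at 1.885 CPM against 0 in the other 3. Control replicate 3 stood apart in Ddx58, at 37.5 CPM against 0.214 to 5.92 CPM, and in Gjc1, at 0.023 CPM (1 count) against 0. Control replicate 1 stood apart in Cmc2, at 51.8 CPM against 32.8 to 35.6 CPM.

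Genes at 0 in some libraries and well above 0 in others were common: of genes with a mean of 5 to 10 CPM, at least 2.49% were at 0 in every library of 33311665 counts or more, where counting alone predicts almost none, so sequencing depth by itself does not account for the zeros. In 6 genes all 4 libraries of one group were at 0 and each library of the other had 3 or more counts, among them Manba and Gm15283 (0 in the controls) and Tgif1, Mterf2 and Gm7575 (0 in the knockdown-labelled libraries), chosen after their values were seen. These 6 genes are fewer than the median of 9 over the other splits of the 8 libraries, and 31 of the 35 splits gave as many (highest other 13), which argues against the Polq guide as the source of an excess of such genes. A small number of RNA molecules captured before amplification may account for the zeros: variation between libraries fell with abundance with a log-log slope of −0.643 in the controls and −0.665 in the knockdown-labelled libraries, shallower than the −1 that random capture alone would give, and the implied number of molecules differed 1.16-fold between groups whose median depth differed 4.53-fold. That slope lies outside the range set for this explanation without reaching the bound set against it, so random capture and differences between embryo pools cannot be told apart here.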

How the results depend on the processing

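Thinning to the smallest total, leaving out knockdown-labelled replicates 1, 2 and 3, the filter at 50 CPM and sample quality weights were chosen after seeing the data. EdgeR and limma-voom called 0 genes in either direction under each of their settings, and DESeq2 called 14 higher and 6 lower; the cause was not tested. Polq stayed negative and short of the threshold under 20 of 21 settings (log2 fold change −0.47 to −0.11 with 1 library left out). It was 0.073 with replicate 4 as the only knockdown-labelled library, which is assumed to vary like the controls, and had no value with the filter at 50 CPM, which it does not pass. The count of lists past the threshold, 1 in the reported test, was 1 under 6 settings (with only replicate 4 kept, that list was the oviduct and blood markers), 2 with the stricter filter on low counts (ribosomal proteins and nucleolar genes), 0 to 3 with 1 library left out, 0 with an estimated correlation and 0 with fry; the cause was not tested. Same-numbered samples did not deviate together (correlations −0.08 to 0.01, and 1 of 8 samples correlated best with its own number). No pairing by number was therefore seen, though a weak shared effect could be hidden by the spread between libraries. With the replicate number as a block, 0 lists passed (smallest adjusted p 0.144, for ribosomal proteins). In that fit 0 genes were called higher and 0 lower, and Polq was at −0.38. The Ddx58 log2 fold change turned positive in limma-voom (0.13), with the block (0.35) and without control replicate 3 (−1.76 to 0.58 with 1 library left out). The Tnfaip6 log2 fold change turned in limma-voom (0.35) and without control replicate 2 (range −3.23 to 0.23), as did the Amhr2 log2 fold change without control replicate 2 (range −0.025 to 0.71), the Ldhc log2 fold change without knockdown-labelled replicate 3 (range −0.44 to 0.71) and the Tekt1 log2 fold change in limma-voom (0.50); the left-out library held the highest or lowest value in its group where one was left out. Of the other values of named genes 782 kept their direction and their side of the threshold, and 2 passed in DESeq2 (Gjc1 and Ino80e). Of the list medians 310 moved by less than the spread between libraries and 2 by more, but that spread is wide beside the medians (for ribosomal proteins an SD of 0.28 and a median of 0.15). In 14 of 26 lists the median took the other sign without 1 library, among them interferon (−0.20 to 0.60), homologous recombination (−0.076 to 0.055) and p53 targets (−0.31 to 0.098), and the ribosomal median ran from 0.061 to 0.31. The stricter filter turned the medians of p53 targets (0.0068), interferon (0.12), integrated stress (0.15), 2-cell burst (0.032), epigenetic (−0.045), cumulus (0.33) and oviduct and blood genes (−0.046), and the block those of epigenetic (−0.053) and cumulus genes (0.045). Depth leaves the most counting error in knockdown-labelled replicate 1, with 85 Polq counts; thinning all libraries to its total left Polq at −0.32.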

Other observations

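Of the tests in this part, those of splits for the counts of genes, of the zygotic lists and of swapped libraries were chosen after related values had been seen. The tests of splits for the ribosomal protein list, of exonic length and of the spread of Polq were fixed before their results. The genes named in the next paragraph, the most abundant of their lists or of the libraries and some of the low members of the same lists, were chosen after their values were seen.

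The RNA of these embryos was led by mitochondrial and maternal transcripts in both groups. The mitochondrial cytochrome b mRNA mt-Cytb took 7.75 ± 1.29% of the TMM-scaled counts of tested genes in the controls and 8.11 ± 2.51% in the knockdown-labelled libraries (SD, n = 4). Dppa3, a maternal factor that protects DNA methylation in the zygote, took 3.67 ± 0.330% and 3.54 ± 0.657% on the same scale. Omt2a and Omt2b, whose counts are uncertain because they belong to a family of near-identical copies, took 2.41 ± 0.430% and 3.09 ± 0.526% of TMM-scaled control counts. Levels differed widely within a list, in CPM, which is not corrected for transcript length. In classical end joining the most abundant member was Rif1, which directs breaks to that pathway, at 417 ± 75.8 CPM in the controls and 431 ± 37.99 CPM in the knockdown-labelled libraries, while Xrcc4 was at 31.3 ± 12.8 CPM in the controls. In homologous recombination it was Brca2, at 410 ± 58.1 and 420 ± 21.3 CPM, while Palb2 was at 18.5 ± 2.77 CPM and Eme1 at 11.8 ± 5.76 CPM in the controls. The alternative end joining list summed to 542 ± 34.4 CPM in the controls, of which the damage kinase Atm made up 225 ± 52.5 CPM and Polq 39.3 ± 7.65 CPM. In the G2 and M phase list Cks2 was at 6931 ± 1777 and 6995 ± 638 CPM, while Ccnb2 was at 8.49 ± 4.45 CPM in the controls, and in the S phase list the replication licensing inhibitor Gmnn was at 2974 ± 530 and 3322 ± 121 CPM, while Gins3 was at 14.6 ± 6.96 CPM. Levels were not compared between lists by a test. Brix1, a ribosome assembly factor, was at 2706 ± 404 and 2776 ± 474 CPM, and Btg4, which triggers the removal of maternal mRNA, at 1579 ± 538 and 1373 ± 456 CPM. None of these genes passed edgeR's test between the groups.

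The real groups gave 0 genes past the threshold in edgeR, so that each of the 35 splits of the 8 libraries into 4 and 4 had to give as many (35 of 35, highest other 0), and this count says nothing about chance. At an unadjusted p under 0.05 chance cannot be excluded: the real groups gave 369 genes, 12 of the 35 splits gave as many, and the highest other split gave 933.

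The higher level of ribosomal protein genes in the knockdown-labelled libraries, with nucleolar genes in the same direction, has a real camera p of 0.000778 with the preset correlation, and of 0.499 (adjusted p = 0.921) with an estimated one. Of the 35 splits 11 gave a p as small, the smallest of the others 3.28e-14, so chance cannot be excluded. With the preset correlation 24 of the 35 splits called at least 1 list, so such a call is not particular to the real groups. The cause of these calls was not tested. Lists matched on exonic length and abundance did not move alike. The ribosomal protein list's median log2 fold change of 0.15 was above the medians of all 10000 matched lists (percentile 100), whose middle 95% ran from −0.11 to 0.03. Exonic length here covers all annotated exons of a gene and can exceed the length of its mRNA. Matched genes were also drawn independently of each other, while the members of the ribosomal protein list correlate. A bias by transcript length therefore cannot be excluded. A hypothesis is that the knockdown-labelled pools were further along in genome activation. The prediction set for it was that both zygotic lists outside the pattern are higher in these pools. The mean log2 level of the other zygotic genome activation genes was 5.47 ± 0.12 in the controls and 5.64 ± 0.098 in the knockdown-labelled libraries. The exact permutation p was 0.0571, and 0.743 when adjusted over the lists. The heat shock and unfolded protein response list had the same exact permutation p in the other direction. The 2-cell burst genes were at 5.59 ± 0.39 and 5.60 ± 0.49 (exact permutation p = 1). They are transcribed briefly at this stage, so pools further along could have them higher or lower, and their level cannot decide this. The maternal oocyte transcripts were lower, at 6.42 ± 0.19 and 6.16 ± 0.29 (exact permutation p = 0.2, adjusted 0.912). This explanation and chance cannot be told apart with 4 libraries in each group.

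Polq was not separated between the groups, and ordinary library noise may be enough to leave its interval wide: the spread of Polq within groups lay at the 27.9 percentile of 699 genes of like abundance. Swapped labels stay open: in 0 of 16 pairs did each library correlate better with every library of the other group than with any of its own, but correlations within groups (0.696 to 0.767) and between groups (0.702 to 0.760) covered the same range. By mean correlation, knockdown-labelled replicate 1 was slightly closer to the controls (0.741) than to its own group (0.739). Control replicates 1, 3 and 4 were closer to the knockdown-labelled libraries (0.731, 0.742 and 0.751) than to the other controls (0.721, 0.737 and 0.739). The remaining libraries were closer to their own group. Knockdown-labelled replicates 2, 3 and 4 were at 0.738, 0.749 and 0.748 with it, against 0.720, 0.739 and 0.738 with the controls. Control replicate 2 was at 0.719 against 0.715. Polq lay inside the control range in knockdown-labelled replicates 2 and 4, and was lowest in replicate 1 (16.9 CPM). A partial knockdown, down to 47.8% of the control level, stays open as well, and protein levels were not measured here.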
